A study of Homo sapiens with 12 samples.

How the data were processed

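RNA was measured in 12 libraries from 2 established human colorectal cancer cell lines, COLO320DM and SW480. Each line was transfected with a plasmid that expresses HKDC1 under the CMV promoter (pCMV6-HKDC1) or with the matching empty vector (pCMV6-Entry), with 3 replicates in each of the 4 groups. The labels' protocols give 10 µg of plasmid, Lipofectamine 2000, and a medium change that ended the transfection after 24 hours. They describe poly-A selection of RNA with an integrity number above 8 and random-primed cDNA, and mention no step that marks strand. The labels do not say whether the replicates are separate cultures, so the p-values measure the spread between these samples.

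The values are raw counts per gene, deposited by the authors as 1 table with an Ensembl identifier, a position and a whole-number count per library. The submitters' processing notes name HISAT2 2.1.0, limma and the genome build GRCh38, without saying which step used which tool. The read counter, the annotation release and the strand setting were not given in the sources used here. All 60623 genes of the table carry an identifier, and no unassigned-read entry was present. Of these identifiers, 58516 were found in GENCODE 29, and 46623 of those (79.7%) had the same start and end. A total of 58584 had a symbol in the reference tables. Coordinates are those of the deposited table on GRCh38, and exon and coding positions come from GENCODE 29 on the same build. As a check of how overlapping genes were counted, 361 of 366 genes nested in a gene on the opposite strand (98.6%) had counts, with a median read density 1.56 times that of their host. Antisense partners and their hosts are therefore treated as not separable, and so are near-identical copies and pseudogenes. Library totals ranged from 33790733 to 45451279 counts. Intervals and floors given for counts cover counting error only.

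All 12 libraries entered 1 model with 4 group means in edgeR 4.0.16 (R 4.3.3), with genes kept by filterByExpr (minimum count 10, minimum total 15), TMM factors and robust dispersions. This left 23684 genes. Quasi-likelihood F tests (glmQLFit, glmQLFTest) gave the plasmid effect in each line, the difference between these effects, their mean, and the difference between the lines with empty vector. Benjamini-Hochberg adjusted p-values under 0.05 were called. The libraries share an estimate of the spread with 8 residual degrees of freedom, and the biological coefficient of variation was 0.157. CPM values are scaled by TMM, except for HKDC1, AL596223.2 and the other hexokinases, whose CPM are over the library total. SD is over the 3 libraries of a group. SE is the size of the fitted log2 fold change divided by the square root of its F statistic. Single-gene comparisons of 3 against 3 libraries used an exact two-sided permutation test, whose smallest p is 0.1. A fold against a group with 0 counts in all libraries is a lower bound, computed from a floor of 3 counts over the group.

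The labels number the replicates 1 to 3 in every group, so the pairing was checked before calls were compared. Deviations from the group means correlated between same-numbered libraries at 0.40, 0.13 and 0.12 in COLO320DM and at 0.72, 0.44 and 0.31 in SW480, each over 0.1. Replicates 2 and 3 correlated as well across numbers (0.15 and 0.16 in COLO320DM, 0.37 and 0.47 in SW480), and replicate 1 correlated with neither (−0.25 to −0.22 and −0.58 to −0.44). The pairing thus comes from the data and mostly separates replicate 1 from replicates 2 and 3. Between libraries of a group, chi-squared per degree of freedom was 3.18 to 10.1 for replicates 2 and 3. It was 24.5 to 82.9 for replicate 1 against either, over genes with at least 40 summed counts. Pairs 2 and 3 of a line may thus not be independent. Counts of agreeing pairs and paired p-values take every pair as independent, and may overstate the evidence. The same model was fitted again with the replicate number within each line as a block (called the replicate block or paired fit), with 4 residual degrees of freedom and a biological coefficient of variation of 0.06. Paired results are given where they change a call or move a count by over 1.5 times.

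A set of 31 gene lists was fixed before the data were examined, together with the tests, the rule for named genes and the alternatives, except those said to be added later. The lists cover glycolysis and glucose transport, the pentose phosphate and hexosamine pathways, the TCA cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, DNA replication and G1/S, mitosis and G2/M, cyclins and CDK inhibitors of G1, MYC target genes, cholesterol synthesis, fatty acid and lipid synthesis, ER stress, the ATF4 integrated stress response, the interferon response, NF-κB and inflammatory cytokines, p53 target genes, apoptosis regulators, hypoxia and HIF target genes, WNT and β-catenin target genes, immediate early and MAPK output, heat shock proteins, NRF2 and oxidative stress, autophagy and lysosome, epithelial and colonic identity, mesenchymal and EMT genes, neuroendocrine genes, cytosolic ribosomal proteins, replication-dependent histones (not polyadenylated), and markers of fibroblasts, leukocytes and endothelial cells. Lists were tested with camera in limma 3.58.1 on voom-weighted log2 CPM, with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were run as alternatives. For each list, members were counted as called over all genes tested and as adjusted over the list alone.

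Named genes are HKDC1 and the other hexokinases and, for each plasmid contrast, up to 10 genes per direction of the largest change among called genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, clone-style names left out. Where fewer than 5 passed, the 5 of smallest p are given as not past the threshold. From each list, up to 4 members of smallest p are named per contrast, and for the comparison of the lines list members only. For the paired fit, no overlap between groups was replaced by the same direction in every pair, a rule chosen after the data were examined.

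Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios (RLE) size factors, library totals, no count filter, a filter of CPM at least 1 in 3 libraries, a log2 fold change of at least 1, the replicate block, only the 6 libraries of a line, and leaving out each library. Added after seeing the data were a term for replicate 1 against the others, replicates 2 and 3 alone, and the alternatives of the paired fit. The fits were tested on simulated counts with the real library sizes, with 50 genes changed at each of 4 fold sizes. Means came from the paired fit with the plasmid effect taken out, and dispersions from the paired fit. Replicate effects were thus the same in both plasmid groups. The recovered and false calls therefore do not test the paired fit where a plasmid change differs between pairs. For SW480, the unpaired fit recovered 0, 13, 40 and 49 of the 50 genes changed by 1.2, 1.5, 2 and 4 times among 23398 genes, with 0 false calls. The paired fit recovered 16, 46, 50 and 50, with 8 false calls. For COLO320DM the unpaired fit recovered 0, 16, 40 and 49 and the paired fit 20, 43, 50 and 50 with 14 false calls. In the list test, a simulated list of 20 raised genes was called, and 0 of the 31 fixed lists were. The simulated genes were drawn independently of each other, so this does not test lists whose members are correlated.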

Results

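Gene expression was profiled by poly-A RNA sequencing in COLO320DM and SW480 colon cancer cells after transfection with an HKDC1 expression plasmid or with the empty vector, to look for expression changes that could contribute to proliferation. COLO320DM is a poorly differentiated colorectal line with neuroendocrine features and amplified MYC, and SW480 is a line from a primary colon adenocarcinoma. HKDC1 (hexokinase domain containing 1) is a member of the hexokinase family, the enzymes that phosphorylate glucose at the entry to glycolysis. Each of the 4 groups had 3 libraries. In COLO320DM the libraries held 41007036, 40238322 and 41594070 counts with empty vector and 40733725, 34795261 and 33790733 with the HKDC1 plasmid. In SW480 they held 41926575, 35911723 and 45451279 counts with empty vector and 38966920, 41140908 and 35116239 with the HKDC1 plasmid. Mitochondrial genes took 7.59–9.4% of the counts in COLO320DM and 6.32–7.4% in SW480. The cell line separated the libraries on the first principal component, with 93.1% of the variance. Within a line, the first component separated replicate 1 of both plasmid groups from replicates 2 and 3 (34.3% of the variance in COLO320DM and 60.9% in SW480). The second component (21.8% and 12.5%) placed every HKDC1 library above every empty-vector library of its line. HKDC1 and AL596223.2 were included in the components, so the transfected gene itself can contribute to this separation, by an amount not measured.

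**Figure D1:**
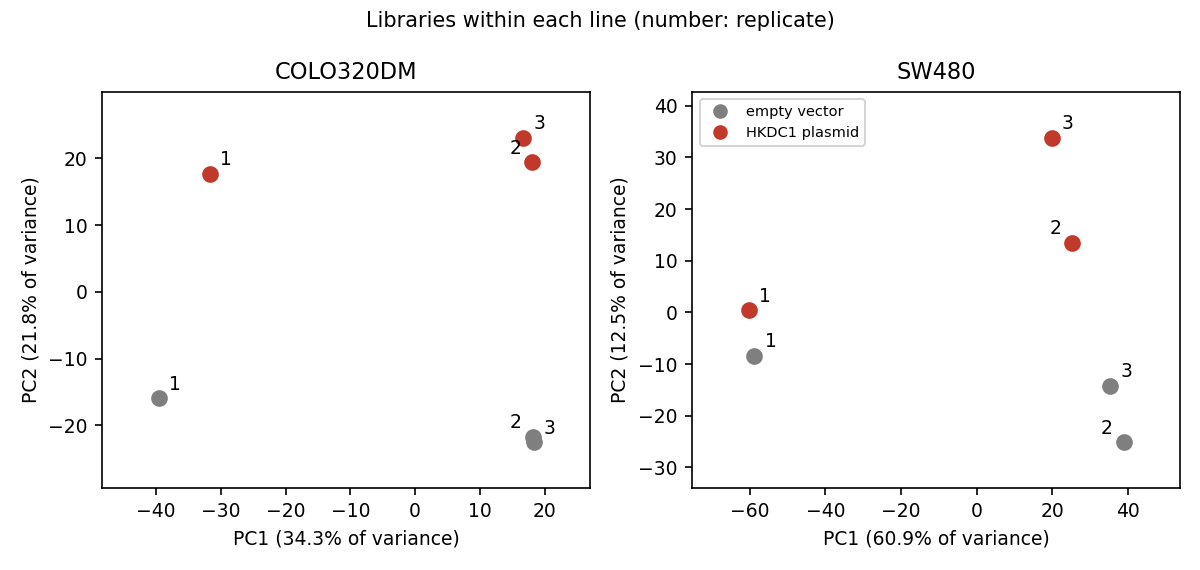
Scores of the 6 libraries of each line on the first and second principal components of log2 CPM, 1 panel per line, with the share of variance on each axis; points are libraries, coloured by plasmid and numbered by replicate. Replicate 1 of both plasmid groups lies apart on the first component, which holds 34.3% of the variance in COLO320DM and 60.9% in SW480.

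The transfected gene was examined first. HKDC1 (ENSG00000156510, chromosome 10, 69220332–69267552 on GRCh38, plus strand, 18 exons) was close to absent from COLO320DM and expressed at a modest level in SW480, and it became the main hexokinase transcript of both lines with the plasmid. In COLO320DM it rose from 0.0163 ± 0.0141 CPM (SD, n = 3; 0, 1 and 1 counts) to 8635 ± 1760 CPM (n = 3). The ratio of the scaled counts was 523000, with a 95% counting interval of 145000–4320000 that reflects the 2 counts of the control group. In SW480 it rose from 35.0 ± 0.769 to 12880 ± 1170 CPM (n = 3 each), a ratio of 367 (95% counting interval 356–378). The edgeR log2 fold change was 8.55 (SE 0.20, adjusted p = 5.28e-11) in SW480 and 18.78 (SE 0.32, adjusted p = 1.08e-12) in COLO320DM, where its size depends on the prior count. The SE in COLO320DM comes from the F statistic and does not cover the counting error of the 2 control counts. The libraries of the groups did not overlap in either line (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give). With the plasmid, HKDC1 took 0.662–0.986% of all counts in COLO320DM and 1.22–1.42% in SW480, and 97.1–98.1% of the counts of the hexokinase genes. With empty vector its share of hexokinase counts was 0–0.01% in COLO320DM and 10.6–10.9% in SW480.

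No difference in the other hexokinases passed the test. HK2, the inducible isoform of many tumours, had 107.3 ± 2.41 CPM with empty vector and 112.2 ± 8.15 CPM with the HKDC1 plasmid in COLO320DM, and 159.2 ± 7.56 and 150.2 ± 6.84 CPM in SW480 (n = 3 each). HK1, the widely expressed isoform, had 37.98 ± 6.65 and 40.39 ± 5.06 CPM in COLO320DM and 73.09 ± 2.53 and 70.35 ± 0.615 CPM in SW480. ADPGK, which phosphorylates glucose with ADP, had 42.78 ± 2.53 and 43.4 ± 0.96 CPM in COLO320DM and 57.68 ± 7.2 and 55.67 ± 2.91 CPM in SW480. The values of these 3 genes in the edgeR test were close to 0 (log2 fold changes of −0.06 to 0.12, adjusted p = 1 in both lines). Without replicate 1 of the empty-vector group, the sign of the HK1 value turned in both lines (−0.02 in COLO320DM and 0.02 in SW480), and without SW480 empty-vector replicate 2 that of ADPGK in SW480 turned (0.03). HK3 had 0–3 counts per library, too few to detect a difference. The antisense gene AL596223.2 (ENSG00000231748, chromosome 10, 69265342–69268148, minus strand), singled out after its values were seen, was the other gene called in both lines in the unpaired fit. It had 0 counts with empty vector and 118311 summed counts with the plasmid in COLO320DM (at least 44300-fold higher, from a floor of 3 counts over the group), and 2.605 ± 0.198 and 1581 ± 195 CPM in SW480 (ratio 600, 95% counting interval 538–672). Its second exon overlaps HKDC1 exon 17 over 143 bases (69265585–69265727), its count was 11.7–12.9% of the HKDC1 count with the plasmid, and reads of overlapping antisense genes cannot be told apart in these counts.

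**Figure D2:**
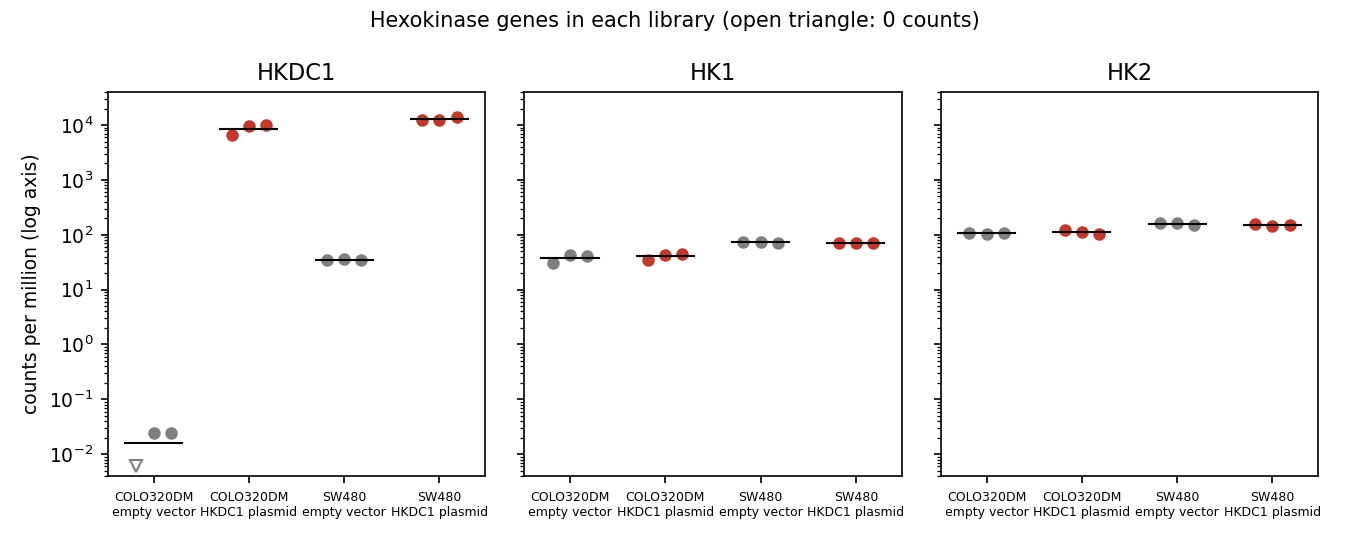
HKDC1, HK1 and HK2 in CPM over the library total (log axis), 1 panel per gene; points are libraries (n = 3 per group), horizontal lines are group means and the open triangle marks a library with 0 counts. HKDC1 rises from a mean of 35.0 to 12880 CPM in SW480, while HK1 and HK2 have no difference that passed the test.

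The comparison in COLO320DM asks what else followed HKDC1 in a line that lacked it. With the replicate block, DNAJB1 (an HSP40 co-chaperone of HSP70) rose, and PIBF1, GH1, FAM13B, ZMYM5, a histone H4 pair and several pseudogene transcripts fell. DNAJB1 had 56.44 ± 2.22 CPM with empty vector and 72 ± 2.02 CPM with HKDC1 (n = 3 each; log2 fold change 0.35, SE 0.06, adjusted p = 0.00688, higher in 3 of 3 pairs). PIBF1, a centrosomal protein gene, fell from 161.6 ± 5.4 to 127.6 ± 6.8 CPM (log2 fold change −0.34, SE 0.06, adjusted p = 0.00688). GH1 had 2.958 ± 0.441 and 1.442 ± 0.52 CPM (log2 fold change −1.06, SE 0.19, adjusted p = 0.00688). GH1 encodes growth hormone, whose polyadenylation signal is part of pCMV6 vectors, and it overlaps AC127029.3, which had nearly the same counts. FAM13B (−0.40), ZMYM5 (−0.39), CCT6P1 (−0.47), MRPS31P5 (−0.38), H4C14 and H4C15 (−0.35 each), SMG1P5 (−0.34) and SMG1P2 (−0.30) were lower in 3 of 3 pairs with adjusted p of 0.00882 to 0.0343. CCT6P1, MRPS31P5 and both SMG1 entries are pseudogenes, so reads can be split among copies. H4C14 and H4C15 are near-identical copies with nearly the same count in every library, so they cannot be read as separate signals. AL671762.1, a noncoding readthrough that starts within HSPA1B, rose in both lines (log2 fold change 0.38 in COLO320DM and 0.46 in SW480) and was named after its values were seen.

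Without the block, edgeR called 2 genes in COLO320DM, HKDC1 and AL596223.2, with 312 genes at an unadjusted p under 0.05. DESeq2 and limma-voom also called 2. With the replicate block, 18 genes were called (4 higher and 14 lower; 1292 at an unadjusted p under 0.05), against 13 by DESeq2, 4 by limma-voom and 32 with no count filter. Apart from HKDC1 and AL596223.2, the genes of smallest p in the unpaired fit did not pass it (adjusted p = 1). On the higher side they were GAS6, a ligand of the TAM receptor kinases (log2 fold change 0.43), GPR84-AS1 (0.53), ENDOD1 (0.31), the collagen gene COL5A1 (0.40) and BTN3A1 (0.21), and on the lower side CCT6P1 (−0.46), PIBF1 (−0.34), GH1 (−1.04), ARID4A (−0.32) and CCT6P3 (−0.43). The paired count was 9 without pair 1, 18 without pair 2 and 7 without pair 3. A check added after seeing the data followed such genes, HKDC1 and AL596223.2 left out, into the left-out pair. For pairs 1, 2 and 3 the slope of that pair on the others was −1.18, −0.29 and 0.41, over 7, 15 and 5 genes. Of these genes 5, 8 and 4 kept their direction, so the paired calls were not shown to repeat in a left-out pair. Without pair 1 GH1 (−0.80, adjusted p = 0.53) and PIBF1 (−0.28, adjusted p = 0.331) no longer passed, and without pair 2 or 3 DNAJB1 did not (0.32 and 0.33, adjusted p = 0.114 and 0.156). Of the other genes named with the block, FAM13B, ZMYM5, CCT6P1, MRPS31P5, H4C14, H4C15, SMG1P5 and SMG1P2, each lost its call without pair 1 and also without pair 2 or pair 3 (adjusted p of 0.0791 to 0.858).

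Among the lists in COLO320DM, glycolysis and glucose transport genes were shifted up as a group: 21 of 24 members had higher values with HKDC1, with a median log2 change of 0.10 (camera adjusted p = 0.0042; adjusted p = 0.92 with an estimated correlation). No member was called over all genes or adjusted over the list alone. The shift was uneven between pairs, with list medians of 0.24, 0.06 and −0.01, and with the replicate block its call was lost without pair 1 (median 0.04, camera adjusted p = 0.19). Heat shock proteins, the chaperones induced by misfolded protein, were shifted up too, with 14 of 16 members higher and a median of 0.08 (camera adjusted p = 0.021; adjusted p = 0.92 with an estimated correlation). With the replicate block, 11 lists were called, 10 up and 1 down, and the estimated correlation gave adjusted p of 0.44 to 0.51 for all of them. Glycolysis (camera adjusted p = 2.1e-07, 22 of 24 higher) and heat shock (8e-09; DNAJB1 the 1 member called over all genes and adjusted over the list alone) stayed called. Cholesterol synthesis (3e-04, 22 of 24 higher), mitochondrially encoded mRNAs (0.0017), ER stress (0.0094), DNA replication (0.0095), mitosis, MYC targets, fatty acid synthesis and WNT targets (0.012 each) joined them with medians of 0.03 to 0.07. In these 8 lists no member was called over all genes or adjusted over the list alone. Replication-dependent histones were lower (camera adjusted p = 0.02, 2 members called over all genes, the near-identical H4C14 and H4C15, and 3 adjusted over the list alone), although their mean (0.07) has the opposite sign to their median (−0.14). Their transcripts lack poly-A tails. The count of called lists without the block was 9 without empty-vector replicate 1, 6 without empty-vector replicate 3, and 5, 10 and 4 without HKDC1 replicates 1, 2 and 3, and with the block it was 6 without pair 1.

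SW480 cells, which express HKDC1 on their own, showed a rise of the chaperone gene HSPA6 with the plasmid. HSPA6, a strictly inducible HSP70 (ENSG00000173110, chromosome 1, 161524540–161526894), rose from 0.872 ± 0.378 to 6.76 ± 1.1 CPM (n = 3 each; log2 fold change 2.95, SE 0.30, edgeR adjusted p = 0.00186). Its counts were 50, 21 and 34 with empty vector and 226, 240 and 279 with HKDC1. Reads can be shared with its near-copy HSPA7, named after its values were seen, which had 12, 4 and 13 counts with empty vector and 41, 58 and 63 with HKDC1. With the replicate block, DNAJB1 (0.33, SE 0.06, adjusted p = 0.00168) and HSP90AA1, the inducible HSP90 (0.32, SE 0.06, adjusted p = 0.00321), rose as well, each in 3 of 3 pairs. Among genes named by the rule, the largest decreases with the block were those of SLIT1, KRT16 and TRPV6. SLIT1, an axon guidance ligand, went from 5.44 ± 2.46 to 2.62 ± 0.835 CPM (log2 fold change −1.02, SE 0.15, edgeR adjusted p = 0.000206). The stress keratin KRT16 had −1.02 (SE 0.18, edgeR adjusted p = 0.00321). The calcium channel TRPV6 went from 11.5 ± 5.88 to 5.45 ± 1.47 CPM (−1.01, SE 0.14, edgeR adjusted p = 0.000111). In the empty-vector group, replicate 1 already had the lowest count of each. The 3 libraries had 105, 276 and 276 counts of SLIT1, 86, 245 and 307 of KRT16, and 193, 603 and 599 of TRPV6.

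Other genes named by the rule in SW480 with the block had the same direction in 3 of 3 pairs. Lower were LAMP3, a lysosomal membrane protein (−0.95), the WNT ligand WNT7B (−0.95), the peptide hormone UCN2 (−0.92), the stress-induced NIBAN1 (−0.92), the AT-hook transcription factor AKNA (−0.90, from 28.6 ± 17.9 to 14.4 ± 6.94 CPM), the protease inhibitor SERPINE2 (−0.79) and C10orf55 (−0.79), with adjusted p of 1.64e-06 to 0.0194. In the empty-vector group, replicate 1 already had the lowest count of each of these lower genes. The 3 libraries had 325, 1561 and 1580 counts of AKNA and 70, 644 and 726 of LAMP3. Higher were LIX1 (0.51), the stearoyl-CoA desaturase SCD5 (0.46), the WNT antagonist DKK4 (0.40), FAM111B, a replication-associated protease (0.33), PCYOX1 (0.32) and FAM81A (0.32), with adjusted p of 0.00731 to 0.0456. Replicate 1 with empty vector already had the highest count of SCD5, FAM111B, PCYOX1 and FAM81A, and the lowest of LIX1 and DKK4. The 3 libraries had 2133, 770 and 1153 counts of FAM111B and 84, 145 and 201 of LIX1. Genes of smallest p in the unpaired fit that did not pass it (adjusted p = 1) were AK7 (0.50), TRIM2 (0.20), DGLUCY (0.24), VSIG10L2 (0.51) and DBI (0.22) on the higher side, and the scaffold AKAP12 (−0.67), ITPKA (−0.80), PDLIM2 (−0.54), the WNT regulator MCC (−0.40) and LBH (−0.52) on the lower side. With the block, ITPKA (adjusted p = 0.00379), PDLIM2 (0.00746), MCC (0.00617) and LBH (0.0215) passed and AKAP12 did not (0.324).

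In SW480, edgeR without the block called 3 genes (HKDC1, AL596223.2 and HSPA6), with 356 at an unadjusted p under 0.05, limma-voom 3 and DESeq2 4. With the replicate block 180 were called, 39 higher and 141 lower, with 2360 at an unadjusted p under 0.05, a median size of 0.38 on the log2 scale and 12 at 1 or more. DESeq2 with the block called 98, limma-voom 79 and edgeR with no count filter 344. The unpaired count was 5 without SW480 empty-vector replicate 1, and the paired count was 538 without pair 1, 13 without pair 2 and 49 without pair 3, so that most calls rested on pairs 2 and 3. The HSPA6 call held when each library or pair was left out, and was lost in a fit of the 6 SW480 libraries alone (adjusted p = 0.186; 4.43e-19 to 0.0268 over the other alternatives). DNAJB1 (0.28, adjusted p = 0.258), HSP90AA1 (0.22, adjusted p = 0.702), SLIT1 (−0.93, adjusted p = 0.0795), TRPV6 (−0.83, adjusted p = 0.0611) and KRT16 (−0.96, adjusted p = 0.362) no longer passed without pair 2. Of the other genes named with the block, AKNA passed without each pair, NIBAN1 lost its call without pair 2 (adjusted p = 0.262), and LIX1, SCD5, DKK4, FAM111B, PCYOX1, FAM81A, LAMP3, WNT7B, UCN2, SERPINE2 and C10orf55 lost theirs without pair 2 or pair 3 (adjusted p of 0.0664 to 1), as did HSP90AA1 (0.0715) and KRT16 (0.206) without pair 3.

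The gene lists in SW480 place these genes in groups. Heat shock proteins were shifted up, with 15 of 16 members higher and a median of 0.21 (camera adjusted p = 2.2e-05; adjusted p = 0.70 with an estimated correlation). With the block, HSP90AA1, DNAJB1, HSPE1 (0.29, the mitochondrial HSP10) and DNAJA1 (0.31) were called over all genes and 11 adjusted over the list alone (median 0.26, camera adjusted p = 2.5e-18; adjusted p = 0.12 with an estimated correlation). DNA replication and G1/S genes were shifted up in 29 of 30 members, with a median of 0.14 (camera adjusted p = 3.1e-06; 0.70 with an estimated correlation). With the block, 5 members rose, among them the replicative helicase subunit MCM4 (0.28), the sliding clamp PCNA (0.24), the uracil glycosylase UNG (0.31) and GINS1 (0.28), and 13 did adjusted over the list alone (median 0.16, camera adjusted p = 1.4e-15; adjusted p = 0.12 with an estimated correlation). Mitosis genes had 26 of 30 members higher (camera adjusted p = 0.0068; 0.70 or more with an estimated correlation), and with the block 0 were called over all genes by edgeR and 4 adjusted over the list alone (3.5e-08; adjusted p = 0.12 with an estimated correlation). Their median of 0.08 without the block turned to −0.06 without HKDC1 replicate 1 and to 0.00 without empty-vector replicate 2. Cholesterol synthesis was shifted up (0.0071 unpaired; 5.6e-08 with the block, and adjusted p = 0.22 with an estimated correlation), with the enzymes SQLE (0.26), FDFT1 (0.26) and HMGCS1 (0.28) called over all genes and 7 members adjusted over the list alone. With empty vector, replicate 1 already stood apart in the direction of these changes: the 3 libraries had 4927, 1935 and 2173 CPM of HSP90AA1, 345.3, 179.6 and 201.2 of PCNA, 348.9, 159.5 and 175.4 of MCM4, and 109.8, 58.6 and 65.0 of HMGCS1.

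Immediate early and MAPK output genes were shifted down in SW480, with 24 of 27 members lower and a median of −0.16 (camera adjusted p = 3.1e-06; adjusted p = 0.70 with an estimated correlation). With the block, 6 fell, among them the AP-1 subunits FOSL1 (−0.41, from 92.63 ± 20.7 to 68.69 ± 7.79 CPM) and JUNB (−0.29), EGR1 (−0.34) and IER3 (−0.32), and 11 did adjusted over the list alone (camera adjusted p = 4e-14; adjusted p = 0.12 with an estimated correlation). NF-κB and inflammatory cytokine genes were not called without the block (camera adjusted p = 0.17) and were with it (5.2e-16; adjusted p = 0.12 with an estimated correlation), with 17 of 18 members lower and a median of −0.24. Of these, 5 fell over all genes and 8 adjusted over the list alone, among them TNFAIP2 (−0.35), NFKB2 (−0.31), the growth factor CSF2 (−0.65) and the chemokine CCL2 (−0.47, lower in 2 of 3 pairs). The ATF4 integrated stress response was called with the block only (1.3e-08; adjusted p = 0.12 with an estimated correlation), with the stress cytokine GDF15 (−0.42), the mTORC1 inhibitor DDIT4 (−0.24) and the transcription factor DDIT3 (−0.27) lower over all genes and 10 members adjusted over the list alone. With empty vector, replicate 1 already had the lowest levels of these genes: the 3 libraries had 54.0, 530.3 and 484.5 CPM of TNFAIP2, 1.71, 53.2 and 48.8 of CCL2, 187.4, 627.4 and 568.9 of EGR1, and 13.03, 116.8 and 111.9 of GDF15. MYC, a member of the MAPK, WNT and G1 lists, was lower with the block (−0.24, adjusted p = 0.0284). Without pair 2 none of the members named for these lists passed (adjusted p of 0.0931 for CSF2 to 0.907 for HMGCS1), and without pair 3 only DNAJB1, HSPE1, TNFAIP2 and EGR1 did. The list medians of NF-κB genes were 0.10, −0.26 and −0.39 in pairs 1, 2 and 3, and those of heat shock proteins were 0.07, 0.34 and 0.34. The 2 replicates with these larger differences are the ones that lay apart from replicate 1 on the first principal component.

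**Figure D3:**
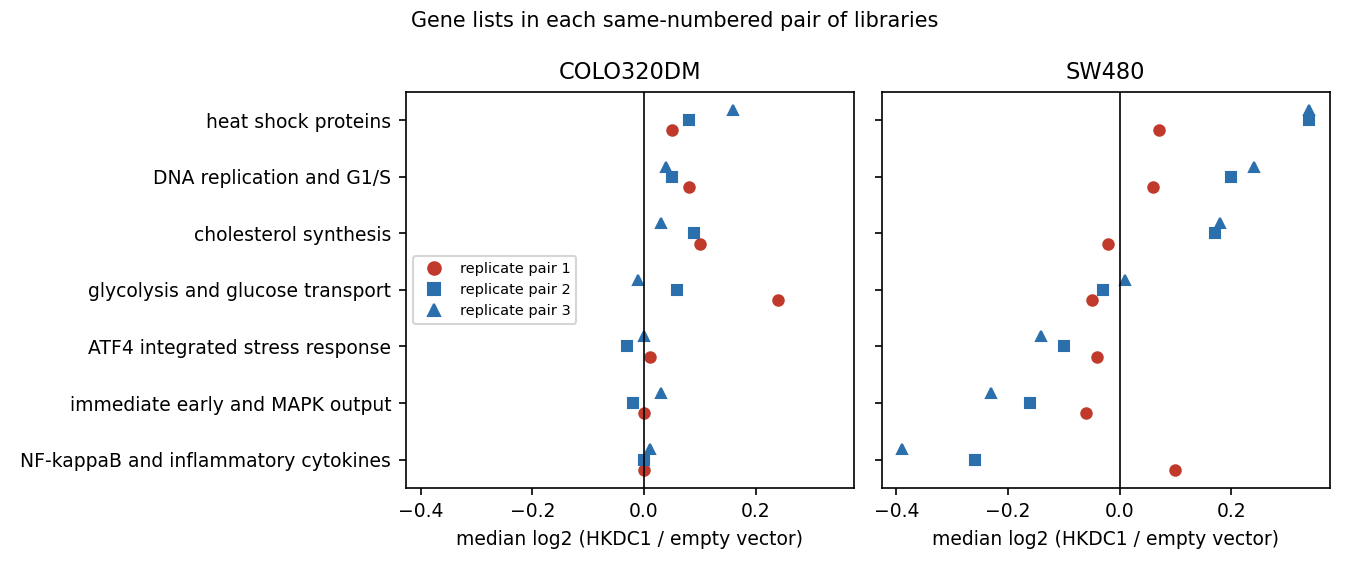
Median log2 change (HKDC1 minus empty vector) over the tested members of selected gene lists in each same-numbered pair, 1 panel per line; each point is a pair. Heat shock proteins (0.05 to 0.34) and DNA replication genes (0.04 to 0.24) lie above 0 in all 6 pairs, while NF-κB genes in SW480 lie at 0.10 in pair 1 and at −0.26 and −0.39 in pairs 2 and 3.

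Further lists were called in SW480. Fatty acid synthesis (camera adjusted p = 0.033 unpaired and 0.002 with the block) and oxidative phosphorylation (0.018 and 0.0054) were shifted up in both fits, with medians of 0.07 and 0.05. With an estimated correlation the adjusted p was 0.70 for both without the block, and 0.14 and 0.38 with it. GPAM, which starts triglyceride synthesis, was called with the block (0.28). Hypoxia targets (0.029 and 5e-04, median −0.10) and mesenchymal genes (0.018 and 0.00058, median −0.16 with the block) were shifted down in both, with NDRG1 the 1 hypoxia member called over all genes with the block (−0.46) and 1 and 5 members adjusted over the list alone. Their adjusted p with an estimated correlation was 0.70 without the block and 0.12 with it. Called with the block only were mitochondrially encoded mRNAs (0.00068, median 0.05), WNT targets (0.0053, median 0.10), p53 targets (0.00098, median −0.04; TNFRSF10B −0.26), autophagy and lysosome genes (0.0049, median −0.14; MAP1LC3B −0.30 and SQSTM1 −0.23), interferon response genes (0.045, median −0.06; IRF1 −0.29) and apoptosis regulators (0.047, median −0.06). For these lists the adjusted p with an estimated correlation was 0.12 to 0.38 with the block. The WNT list, shifted up, holds 1 called member that was lower, MYC. Glycolysis (adjusted p = 0.28), the pentose phosphate and hexosamine pathways (0.56), the TCA cycle (0.073), G1 cyclins (0.081), MYC targets (0.087), ER stress (0.54), NRF2 (0.54), epithelial identity (0.54), neuroendocrine genes (0.28), ribosomal proteins (0.073) and histones (0.28) were not called with the block. The NRF2 list still had GPX2 (0.31) and PRDX1 (0.22) called, both antioxidant enzymes. Each called member named in this paragraph lost its call without pair 2 and without pair 3 (adjusted p of 0.116 for SQSTM1 to 0.998 for PRDX1). Markers of fibroblasts (0.63), leukocytes (0.17) and endothelium (0.29, 2 of 8 tested) were not called. In all, 9 lists were called without the block (6 up and 3 down) and 17 with it (8 up and 9 down). With an estimated correlation or with the directional test of fry, 0 were called in either fit (unpaired, 0 and 0 at an unadjusted p under 0.05; paired, 10 and 13). The test of fry for changes in either direction called 14 lists with the block, hypoxia and immediate early genes with the smallest adjusted p (0.021 each), and 0 without it. In camera, without SW480 empty-vector replicate 1 the unpaired count was 17.

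Whether the plasmid acted differently in the lines was tested directly. With the replicate block, HSPA6 rose more in SW480 than in COLO320DM. The plasmid effect (not the level) of AKNA, EPHA2, EGR1, UNC5B, GTPBP2, FLNA and BMERB1 was lower in SW480 than in COLO320DM in the same fit. HSPA6 had a log2 fold change of 2.97 in SW480 and 0.91 in COLO320DM (difference 2.06, edgeR adjusted p = 0.000526). DESeq2 with the block did not call this difference. AKNA had −0.90 and 0.13 (difference −1.03, adjusted p = 5.63e-05), and the receptor kinase EPHA2 had −0.33 and 0.19 (difference −0.52, adjusted p = 0.00418). EGR1, an immediate early transcription factor, had −0.34 and 0.35 (difference −0.68, adjusted p = 0.0278). The netrin receptor UNC5B had −0.56 and 0.14 (difference −0.71, adjusted p = 0.008), GTPBP2 −0.48 and 0.06 (−0.54, adjusted p = 0.0293), the actin crosslinker FLNA −0.26 and 0.20 (−0.47, adjusted p = 0.0144) and BMERB1 −0.60 and 0.00 (−0.60, adjusted p = 0.0376). Without the block 2 genes were called, HKDC1 (difference −10.23) and AL596223.2 (−9.10), both of which start from 2 or fewer counts in COLO320DM, so that the size depends on the prior count. With the block 10 were called, 1 with a higher and 9 with a lower plasmid effect in SW480. DESeq2 with the block called 13, of which 0 were higher, and limma-voom 4, of which 1 was higher. With no count filter 67 were called, of which 6 were higher. The unpaired test had 379 genes at an unadjusted p under 0.05, and DESeq2 called 3 and limma-voom 2. Genes of smallest p not past the unpaired test were PIK3R3 (0.45), CPSF4L (0.70), C17orf80 (0.31), ARID4A (0.34) and GH1 (1.06) on the higher side and FLNA (−0.46), NOTCH3 (−0.80), AKAP12 (−0.73) and CCDC80 (−0.71) on the lower side, with PEG10 at 0–5 counts per library in SW480. The paired count was 6 without COLO320DM pair 1 or 3 or SW480 pair 2, 32 without COLO320DM pair 2, and 139 and 27 without SW480 pairs 1 and 3. HSPA6 and AKNA passed without each pair. For AKNA, the SW480 empty-vector libraries had 325, 1561 and 1580 counts, so replicate 1 already lay in the direction of the change. Without SW480 pair 2 EPHA2 (adjusted p = 0.101), UNC5B (0.178), FLNA (0.459), EGR1 (0.104), GTPBP2 (0.654) and BMERB1 (0.391) no longer passed, and each of these also lost its call without 1 or more of the COLO320DM pairs (0.0633 to 0.289).

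Among lists, glycolysis was the 1 called for a difference without the block, with a lower plasmid effect in SW480 than in COLO320DM (median −0.10, 18 of 24 members lower, camera adjusted p = 0.018; adjusted p = 0.99 with an estimated correlation). With the block 11 lists were called (3 up and 8 down; adjusted p of 0.57 to 0.83 with an estimated correlation), and the test of fry for changes in either direction called 1, hypoxia targets (adjusted p = 0.022). The plasmid effect on DNA replication (0.00013), mitosis (0.029) and heat shock (0.0018) was higher in SW480 than in COLO320DM. Lower were the effects on glycolysis (0.00039), ATF4 targets (0.00039), immediate early genes (0.00073, EGR1 called over all genes and 3 members adjusted over the list alone), hypoxia targets (0.0012), NF-κB genes (0.0021), autophagy (0.0082), mesenchymal genes (0.013) and ribosomal proteins (0.028). Ribosomal proteins had a median of −0.04, which became 0.01 without COLO320DM pair 1. The unpaired count of 1 list was 6 without COLO320DM empty-vector replicate 1 or 2 or HKDC1 replicate 1, 2 without empty-vector replicate 3 or HKDC1 replicate 3 of that line, 7, 7 and 2 without SW480 empty-vector replicates 1, 2 and 3, and 9, 5 and 0 without SW480 HKDC1 replicates 1, 2 and 3.

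The mean of both effects asks for changes common to the lines. Replicates 2 and 3 lay closer to each other than to replicate 1, so the pairs counted here are not known to be independent. DNAJB1 was higher in 6 of 6 pairs (log2 fold change 0.34, SE 0.04, edgeR adjusted p = 5.31e-06 with the replicate block), as was HSP90AA1 (0.22, SE 0.04, adjusted p = 0.0124). Lower in 6 of 6 pairs were PPP1R15A, which restores translation after stress (−0.28, adjusted p = 0.00177), AMOTL2, a YAP-responsive junction gene (−0.35, adjusted p = 0.00132), the MAPK phosphatase DUSP8 (−0.31), the Krüppel-like factors KLF10 and KLF6 (−0.23 each), H4C14 and H4C15 (−0.28 each) and the pseudogenes PMS2P8 (−0.37) and PMS2P14 (−0.36), with adjusted p up to 0.0459. HSPA1A, the main inducible HSP70, had 120 ± 18.8 and 216.6 ± 10.5 CPM in COLO320DM and 122.9 ± 111 and 250 ± 74.6 CPM in SW480 (n = 3 each) and did not pass in either fit (log2 fold change 0.94, adjusted p = 1; 0.492 with the block), like its near-identical copy HSPA1B (0.92). Without the block 3 genes were called (HKDC1, AL596223.2 and HSPA6), with 360 at an unadjusted p under 0.05, limma-voom 3 and DESeq2 4. With the block 21 were called, 7 higher and 14 lower, a balance that turned with the tool: DESeq2 with the block called 36, of which 34 were higher, and limma-voom 6, of which 5 were higher. With no count filter 85 were called, and 42 with library totals. Other genes of smallest p that did not pass the unpaired test were VSIG10L2 (0.44), SEMA3C (0.42) and CGNL1 (0.24) on the higher side and CCT6P1 (−0.27), PIBF1 (−0.19), LINC01943 (−0.52), CCT6P3 (−0.25) and ANXA3 (−0.26) on the lower side. The unpaired count was 6 without SW480 empty-vector replicate 1. The paired count was 33 and 12 without COLO320DM pairs 2 and 3 and 176 and 10 without SW480 pairs 1 and 2, and HSP90AA1 no longer passed without COLO320DM pair 3 (adjusted p = 0.167) or SW480 pair 2 (0.383) or 3 (0.0734). DNAJB1 and PPP1R15A passed without each pair, AMOTL2 lost its call without SW480 pair 2 (adjusted p = 0.0771), and DUSP8, KLF10, KLF6, H4C14, H4C15, PMS2P8 and PMS2P14 lost theirs without SW480 pair 2 and without COLO320DM pair 3 (0.0702 to 0.512).

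Over both lines, heat shock proteins were the list of smallest p (15 of 16 members higher, median 0.13, camera adjusted p = 1.6e-06; adjusted p = 0.89 with an estimated correlation), and their list median lay above 0 in 6 of 6 pairs. The same held for the medians of DNA replication, mitosis, MYC target and WNT target genes. Those of neuroendocrine genes and histones lay below 0 in all 6 pairs. Also called up without the block were DNA replication (4.9e-06, 29 of 30), mitosis (0.0034, 30 of 30), cholesterol synthesis (0.0053, 23 of 24), fatty acid synthesis (0.013), the TCA cycle, oxidative phosphorylation and WNT targets (0.033 each). Immediate early genes were called down (0.015, 21 of 27 lower). With an estimated correlation the adjusted p of these 9 lists was 0.89 or more. The replicate block raised the count to 17 (12 up and 5 down; adjusted p of 0.19 to 0.46 with an estimated correlation), adding mitochondrially encoded mRNAs (1.9e-06), glycolysis (0.0015), MYC targets (0.0025) and ER stress (0.027) up, and ATF4 targets (3.3e-05), p53 targets (0.0022), NF-κB genes (0.007) and histones (0.018, mean 0.04 against a median of −0.06) down. In that fit 2 heat shock members were called over all genes and 10 adjusted over the list alone, and of DNA replication genes 0 were called over all genes by edgeR and 12 adjusted over the list alone. The unpaired count was 16 without SW480 empty-vector replicate 1, 1 without SW480 empty-vector replicate 2, 0 without SW480 HKDC1 replicate 1 and 4 without COLO320DM empty-vector replicate 2 or HKDC1 replicate 1.

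The fold changes of the lines, which have separate controls, showed no correlation across genes. Over 23682 genes other than HKDC1 and AL596223.2, Pearson's r was 0 and Spearman's rho −0.008 in the unpaired fit, and r was 0.002 with the block. Genes are not independent replicates, so no p is given. With the block, edgeR called 2 of these genes higher in both lines (DNAJB1 and AL671762.1), where independent lists would share 0.0031. It called 0 lower in both, where 0.083 would be shared. With limma-voom and the block, 2 genes were called higher in COLO320DM before HKDC1 and AL596223.2 are left out. Of 178 other genes called in SW480 with the block, 91 had the same sign in COLO320DM, and of 16 called in COLO320DM 11 had the same sign in SW480.

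With empty vector, the lines differed in most genes. Most members of the epithelial list and of the immediate early and MAPK output list were higher in SW480, and MYC was higher in COLO320DM. Epithelial and colonic identity genes were higher in SW480 for 16 of 20 tested members, among them EPCAM (log2 difference 8.15) and the tight junction gene CLDN7 (8.87). The 1 lower member was the intestinal transcription factor CDX2, with 1451 ± 68.2 CPM in COLO320DM and 13.26 ± 8.06 CPM in SW480 (−6.77). NF-κB genes were higher in 17 of 18, immediate early and MAPK genes in 23 of 27, and MYC targets in 20 of 26. MYC itself had 3354 ± 60.7 CPM in COLO320DM and 919.1 ± 15.5 CPM in SW480 (n = 3 each; −1.87, SE 0.09, adjusted p = 8.33e-10). The cyclin CCND1 (4.01), the crypt transcription factor SOX9 (4.36), the epithelial keratin KRT18 (4.87) and the synaptic vesicle sensor SYT1 (9.57) were higher in SW480, and the neuronal hydrolase UCHL1 (−8.21) was higher in COLO320DM. Neuroendocrine genes went both ways, higher in SW480 for 6 of 13 tested members and lower for 4. Of 24 glycolysis genes, 14 were higher in SW480 and 7 lower, with the lactate exporter SLC16A3 at 0.69 ± 0.198 CPM in COLO320DM and 106.7 ± 4.84 CPM in SW480. Altogether edgeR called 16949 of 23684 genes (71.6%), 8828 higher and 8121 lower in SW480.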

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

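The tests in this part were chosen after the results were seen, the splits of the libraries included, except the removal of the replicate axis from the heat shock list, which was set down before its result was seen.

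Genes whose plasmid effect differed between the lines by a test of the difference come first. HKDC1 (SW480 minus COLO320DM −10.23, edgeR adjusted p = 2.33e-08) and AL596223.2 (−9.10, adjusted p = 0.000174) differed in the unpaired fit, because COLO320DM with empty vector held 2 counts of HKDC1 and 0 of AL596223.2. With the replicate block HSPA6, the inducible HSP70, rose more in SW480 (2.06) by edgeR, a difference that DESeq2 with the block did not call. AKNA, a regulator of immune and EMT genes, had −1.03, the netrin receptor UNC5B −0.71 and the immediate early gene EGR1 −0.68. BMERB1 had −0.60, the translation GTPase GTPBP2 −0.54, the ephrin receptor EPHA2 −0.52 and the actin crosslinker FLNA −0.47. HSPA6 and AKNA kept their call without each pair, and the other 6 lost it without SW480 pair 2. In SW480 with empty vector, replicate 1 already held fewer counts of AKNA (325) than replicates 2 and 3 (1561 and 1580). Splits of the plasmid labels cannot test HKDC1 and AL596223.2, whose counts the transfection fixes, and the unpaired fit called 0 others (edgeR; with these 2, 379 genes at an unadjusted p under 0.05, and 3 called by DESeq2 and 2 by limma-voom). With the block 3 of 32 swaps within pairs called at least the 8 other genes of the real labels (highest other 19), so chance cannot be excluded for that count.

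AL596223.2 lies antisense to the end of HKDC1, and its counts rose with the plasmid in both lines. Its share of the HKDC1 count was nearly constant over the 6 HKDC1 libraries (highest over lowest 1.11), as reads of the plasmid transcript counted for the antisense gene would give, so a candidate source is the plasmid itself. Raised transcription of AL596223.2 cannot be told apart from this, because 291 of its bases lie outside the HKDC1 coding exons and the counts do not say where the reads fall.

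Heat shock proteins, chaperones under the transcription factor HSF1, were higher with the HKDC1 plasmid in 6 of 6 pairs (list medians 0.05 to 0.34), a pattern picked from 31 lists. Medians above 0 in every pair were also found for DNA replication, mitosis, MYC target and WNT target genes. The pairs are not known to be independent, since replicates 2 and 3 lay closer to each other than to replicate 1. For the heat shock list, the share of counts taken by HKDC1 is argued against, since it can shift all other genes by at most 0.02 on the log2 scale, against a list median of 0.26 in SW480 with the block. Reads shared among HSPA genes are argued against as the whole source, since the 12 members outside that family had a median of 0.19. Removing the axis that separates replicate 1 from replicates 2 and 3 left a median of 0.21 over pairs 2 and 3 of SW480 (0.34 before). The pairs taken singly had 0.22 and 0.14. The 95% bootstrap interval of 0.1–0.26 resampled the 16 list members as if independent. It does not measure the spread between libraries or pairs. Part of the shift may thus follow that axis and part may not. The load of an abundant plasmid protein, whatever its function, stays open: HKDC1 took up to 1.42% of a library's counts, and no group expressed another protein.

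Changes called in SW480 with the replicate block came mostly from pairs 2 and 3. An HKDC1 effect of equal size in every pair is argued against as the whole source: over 534 genes called without pair 1, the slope of pair 1 on the others was 0.13, with 69.1% of signs shared. Genes chosen for their change in the other pairs lower such a slope even for an equal effect, by an amount not measured. The slope was 0.72 over 10 genes for pair 2 and 1.08 over 46 genes for pair 3, each left out in turn. The changes followed the difference between replicate 1 and replicates 2 and 3 (lowest of 4 Spearman's rho 0.31 across 14902 genes; −0.02 to 0.14 in COLO320DM). A shift of the HKDC1 cultures along that axis is therefore a candidate explanation, and whether handling or HKDC1 moved them was not tested. Replicate 1 of SW480 already held 9693 counts of HSPA1A with empty vector, against 2049 and 2792 in replicates 2 and 3.

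For the other counts of called genes, splits of the libraries were counted in the same way, without HKDC1 and AL596223.2 in the plasmid comparisons. With 10 splits in each line and for the lines' difference, and 4 swaps within pairs, the splits are too few for a share under 0.05. The real counts and the highest others were 0 and 1 in COLO320DM, 1 and 2492 in SW480 and 16949 and 0 between the lines, and with the block 16 and 1 in COLO320DM and 178 and 15 in SW480. The SW480 split with 2492 sets both libraries of replicate 1 and HKDC1 replicate 3 against the rest, and points to a structure of the libraries (the blocked count is 178). The other 3 splits with both libraries of replicate 1 on the same side called 0 genes (edgeR), so that side alone does not account for it. For the mean effect, 15 of 100 drawn splits, which ignore that structure, called at least the 1 gene of the real split, HSPA6 (highest other 1343), so chance cannot be excluded for that count. With the block 1 of 32 swaps, the real one, called 19 (highest other 16). That is the smallest share that 32 swaps can give. It comes from 1 of several split tests chosen after the results were seen, so it does not exclude chance.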

How the results depend on the processing

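The term for replicate 1, replicates 2 and 3 alone and the alternatives of the paired fit, except the fit without the block, were chosen after seeing the data; the rest were planned.

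HKDC1 kept its direction and its call under every alternative run. Its log2 fold change was 18.27–19.12 in COLO320DM and 8.49–8.59 in SW480 over the left-out libraries, and 18.38–19.05 and 8.52–8.57 over the other settings. Called genes (COLO320DM, SW480, difference, mean) numbered 2, 3, 2 and 3 without the block. DESeq2, limma-voom, RLE size factors, library totals, both filters and a log2 fold change of at least 1 gave 2 to 4. They numbered 18, 180, 10 and 21 with the replicate block, 17, 186, 9 and 21 with a term for replicate 1, 8, 720, 75 and 154 with replicates 2 and 3 only, and 12, 543, 49 and 96 with those and the block. The block lowers the estimated spread from 0.157 to 0.06. For the other settings the cause was not tested. Without each library the counts were 2–2, 3–5, 2–2 and 3–6. Between the lines they were 16073–17600, and 10385 with a log2 fold change of at least 1, a stricter rule by construction.

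With the block, limma-voom called 4, 79, 4 and 6 genes, no count filter 32, 344, 67 and 85, a log2 fold change of at least 1 4, 12, 4 and 4, and no block 2, 3, 2 and 3. DESeq2 called 98 in SW480 and 36 for the mean, and library totals 42 for the mean; the cause was not tested. Without each pair the counts were 7–18, 13–538, 6–139 and 10–176. The correlation of the lines was −0.029 over genes with p under 0.05 in either line (fewer genes) and −0.02–0.022 without each library.

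Called lists numbered 2, 9, 1 and 9 without the block. An estimated correlation and fry (here its directional test) called 0 in each comparison, with 0 lists at an unadjusted p under 0.05 by either; the block gave 11, 17, 11 and 17, and replicates 2 and 3 only 8, 16, 12 and 14. Without each library they were 2–10, 7–17, 0–9 and 0–16. From the paired 11, 17, 11 and 17, an estimated correlation and fry called 0 (1, 10, 2 and 6 lists at an unadjusted p under 0.05 with the estimated correlation; 4, 13, 3 and 7 with fry), and no block 2, 9, 1 and 9. Without each pair they were 6–13, 13–17, 8–12 and 13–18. Camera with a preset correlation of 0.01 takes members as nearly independent, and the estimated correlation was 0.55 for heat shock proteins without the block.

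Direction turned in 10 cases, none past a test. HK1 was −0.02 in COLO320DM without empty-vector replicate 1 (highest without a library 0.21) and 0.02 in SW480 without empty-vector replicate 1 (lowest −0.08), and ADPGK 0.03 in SW480 without empty-vector replicate 2 (lowest −0.09). The mitosis list in SW480 was 0.00 without empty-vector replicate 2 and −0.06 without HKDC1 replicate 1 (highest 0.21), and its mean −0.01 without the latter (highest 0.12). The mean of oxidative phosphorylation was −0.00 with replicates 2 and 3 only, and that of cholesterol synthesis, turned in the test though not in its median, 0.02 without COLO320DM empty-vector replicate 1 (highest 0.16). With the block, mitochondrially encoded mRNAs in COLO320DM were 0.00 (highest 0.09) and ribosomal proteins for the difference 0.01 (lowest −0.10) without COLO320DM pair 1. The cause was not tested. Of the named genes' alternatives in the unpaired fit, 1263 kept direction and side of the threshold, 40 passed it newly and 1 no longer did; in the paired fit 583 kept them and 325 no longer passed.

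Depth limits low genes: HK3 (0–3 counts per library) could not be compared.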

Other observations

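The tests of single members here were planned with the lists, and the paired fit was examined after seeing the data. The list members given here did not pass the edgeR test in the comparison named beside them, and their values show the size of the group shifts. In COLO320DM with the replicate block, the phosphofructokinase PFKL had a log2 fold change of 0.19 (adjusted p = 0.666), the enolase ENO2 0.18 (0.798) and the glucose-6-phosphate isomerase GPI 0.12 (0.911), each higher in 3 of 3 pairs, and the enolase ENO1 0.11 (0.914), higher in 2 of 3. Over both lines, the replication clamp PCNA had 0.16 (adjusted p = 0.0924) and the helicase subunit MCM4 0.17 (0.124), each higher in 6 of 6 pairs. The proliferation marker MKI67 had 0.13 (0.6), higher in 4 of 6 pairs. The heat shock co-chaperone HSPH1 had 0.28 (0.0638) and the mitochondrial chaperonin HSPE1 0.17 (0.0797), each higher in 6 of 6 pairs, and the NF-κB subunit RELB −0.30 (0.0858), lower in 6 of 6.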
